A study of Homo sapiens with 12 samples.

How the data were processed

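Small RNA sequencing of 12 libraries was re-analysed: DLD-1 cells and their sEVs, without and with 10 µM 5-FU for 48 h, 3 libraries in each of 4 groups. Per the labels, small RNA libraries were made with a version 3 small RNA kit and size-selected, and the authors used cutadapt 1.16, FastQC 0.11.9 and Bowtie 1.1.2 with the builds hg19 and hg38, in roles that the labels do not give. The deposited table holds expected counts (expected_counts), which the authors made from the aligned reads as counts per small RNA feature with no scaling to depth, in 14075 features. Of its nonzero values 26.2% are not whole and 73.8% are whole within 1e-09, so reads that match several features appear to have been divided among them. The planned test assumed counts, and the values were therefore rounded to whole numbers, which removed at most 0.001% of the counts of any library. The counting tool and any use of molecular identifiers are not stated, so intervals and floors cover counting error only. Positions in the table are on hg38: of 1610 miRNA features with a position, 1575 (97.8%) lie inside a miRNA gene of GENCODE 29. Of the features, 315 join several genes and 121 miRNAs have more than 1 position, so a value of such a feature belongs to the copies together. Copies kept as separate features, such as RNY4P20 among Y RNAs or RNU1-132P among snRNAs, may share divided reads. Counts of calls and list p-values in such classes therefore do not rest on independent members. Some features called lncRNA overlap embedded small RNA genes, such as RNY5, snoRNAs or tRNAs, and their reads cannot be assigned to either.

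Total counts ranged from 7138152 to 21204801 per library and miRNA counts from 895366 to 10178306. The 10 most abundant features took 52.02 to 77.48% of the counts of a library. Replicates differed by more than counting error, with a chi-square per degree of freedom from 39.6 to 1623.5 between libraries of a group.

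Comparisons, tests, gene lists and the rule for named features were fixed before the data were examined. In 5 comparisons, each feature was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group and Benjamini-Hochberg adjustment at 0.05. The comparisons were 5-FU against none in cells and in sEVs, sEVs against cells without and with 5-FU (6 libraries each), and the difference between the last pair in a fit of all 12 libraries. The biological coefficient of variation was 0.38, 0.36, 0.46, 0.25 and 0.47 in this order. Classes were compared by the log2 share of all counts with exact two-sided permutation tests over 20 arrangements, or 400 for the difference of differences, which tests against no treatment effect in either fraction; the smallest p of 3 against 3 is 0.1. The replicate numbers were not used as pairs, because features of the same number did not vary together (correlations from −0.19 to 0.05). Fold changes are relative to the features a scaling holds level, and no spike-in gives absolute amounts.

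Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, over 13 miRNA lists and the small RNA classes with at least 3 tested members, and again with an estimated correlation and with fry. The lists were the let-7 family, the miR-17~92 cluster and paralogs, the miR-200 family, gut epithelium miRNAs, miRNAs described as p53 targets, in the 5-FU response of colorectal cancer cells, in vesicles by KRAS status or as enriched in vesicles, miRNAs overlapping other small RNA classes, mirtrons and Dicer-independent miRNAs, and miRNAs of blood and serum, of stroma and muscle, and of neural and germ cells. The last 3 stand for other cell types or serum. The snoRNA subsets were H/ACA box (SNORA), C/D box (SNORD) and Cajal body (SCARNA, 3 tested members, not past camera in any comparison). No camera call held with an estimated correlation. Fry, which does not set a list against other features, passed no list for 5-FU in cells (lowest adjusted p = 0.153). It also passed none in the difference of differences (lowest adjusted p = 0.0638). For 5-FU in sEVs, with TMM, fry called miRNAs lower (adjusted p = 0.0144) and snoRNAs and Y RNAs higher (0.00655 and 7.92e-04).

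Features were named by rule: among those past the threshold, with no overlap between replicates of the groups (chance gives 10% of features for 3 against 3) and at least 50 CPM in the higher group, the 6 miRNAs and the 4 features of other classes with the largest change in each direction. For the difference of differences the rule asked in place of no overlap for opposite signs in cells and sEVs or a difference of at least 1 on the log2 scale. The 5 most abundant miRNAs and up to 4 members of each list were added, and only some of these are printed. Any other named feature is said to have been chosen after its values were seen. Normalised CPM are scaled within the comparison they belong to.

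Alternatives were RLE factors in edgeR, total counts, DESeq2 1.42.0, no filter, at least 10 CPM in 3 libraries, a log2 change of at least 1, all 12 libraries in 1 fit, a replicate block (with statmod 1.5.0 installed), miRNA features alone, other denominators of the shares, and leaving out each library. Chosen after seeing the data were counting overlapping lncRNA features with Y RNAs or snoRNAs, and list tests among miRNAs or snoRNAs alone. The pipeline was tested on simulated data: 2-fold changes were recovered for 10.4%, 88.1%, 10.4%, 76.1% and 4.5% of features in the 5 comparisons, in the order above. There few features were changed, at random up or down, so most stayed level, as TMM assumes. The rates therefore do not cover shifts of whole classes, as seen in the comparisons with sEVs. Permutations numbered 100000 with seed 11 where enumeration was not exact. Annotation and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out.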

Results

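Small RNAs were sequenced from DLD-1 cells, a human colorectal adenocarcinoma line, and from the small extracellular vesicles (sEVs) that these cells released. The cells were kept in serum-free medium without or with 5-fluorouracil (5-FU), a fluorinated pyrimidine given against colorectal cancer. The treatment was 10 µM for 48 h by the treatment label, while the growth label states 10 mM. The 4 groups were untreated cells, treated cells, sEVs of untreated cells and sEVs of treated cells, with 3 libraries each. The labels do not say whether the replicates came from separate cultures, so every p measures the spread between samples. Total counts were 17805909, 7138152 and 14127943 in the untreated cell libraries and 15704583, 15118502 and 14445799 in the treated ones. The sEV libraries held 15971160, 21204801 and 14857520 counts without 5-FU and 20675500, 16220993 and 16365825 with it. The table lists 14075 features of 9 classes with positions on hg38, among them 1610 miRNAs, 556 snoRNAs and 59 tRNA families. The study asked whether 5-FU changes the small RNAs, miRNAs above all, that the cells export into sEVs.

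Cells and sEVs differed in the classes of RNA they held. Reads of miRNAs, which guide the silencing of mRNAs, made up 62.9% ± 17.6 (SD, n = 3) of all counts in untreated cells and 16.3% ± 1.11 in their sEVs. Reads of tRNAs made up 4.87% ± 1.52 and 42.4% ± 0.222, and those of Y RNAs, small RNAs bound by the Ro protein, 2.55% ± 0.739 and 27.1% ± 1.59. Reads of snoRNAs, which guide the chemical modification of rRNA, went the other way, with 4.63% ± 2.27 in cells and 0.256% ± 0.0275 in sEVs. With 5-FU the miRNA share of the sEVs was 6.95% ± 1.48, which is 2.37-fold lower (log2 difference −1.25, SD 0.23), and all 3 treated libraries lay below all 3 untreated ones. In the treated cells the miRNA share was 65.6% ± 0.99, a log2 difference of 0.10 with an SD of 0.29. The lncRNA share of the sEVs was 2.98% ± 0.156 without and 5.99% ± 0.232 with 5-FU. It rests on AC073140.2, a feature lying over the Y RNA gene RNY5, which held 2.04% ± 0.0974 and 5.07% ± 0.0774, and the log2 difference of 1.01 became −0.08 in a regrouping that counted that feature as Y RNA and the snoRNA host genes GAS5, SNHG1 and SNHG5 as snoRNA. The sEV share of snoRNAs was 0.354% ± 0.0302 with 5-FU, that of tRNAs was higher with it by 0.24 on the log2 scale, and that of rRNAs was 7.87% ± 0.148 without and 6.39% ± 0.118 with it.

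Each of these differences between sEV groups, and each class difference between sEVs and cells named above, reached p = 0.1 in the exact two-sided permutation test, the smallest p that 3 libraries against 3 allow. The adjusted p over the 9 classes was 0.15 without 5-FU and between the sEV groups, and 0.113 between sEVs and cells with 5-FU. In cells the miRNA share gave p = 0.7 in that exact test. The change of the miRNA share differed between sEVs and cells by −1.35 on the log2 scale, with p = 0.035 over the 400 exact permutations of the treatment labels within cells and within sEVs, and adjusted p = 0.315. Untreated cell replicate 2 had the lowest depth and the highest miRNA share of its group, 81.1% (95% Wilson interval 81.08 to 81.13%, counting error only). Replicates 1 and 3 of that group had 46.07% and 61.61%. Without replicate 2 the difference was −1.55 with adjusted p = 0.045 in the exact permutation test. Without untreated cell replicate 1 it was −1.14 with adjusted p = 0.285 in the same test. Without any other single library the adjusted p of that test ran from 0.225 to 0.441.

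**Figure D1:**
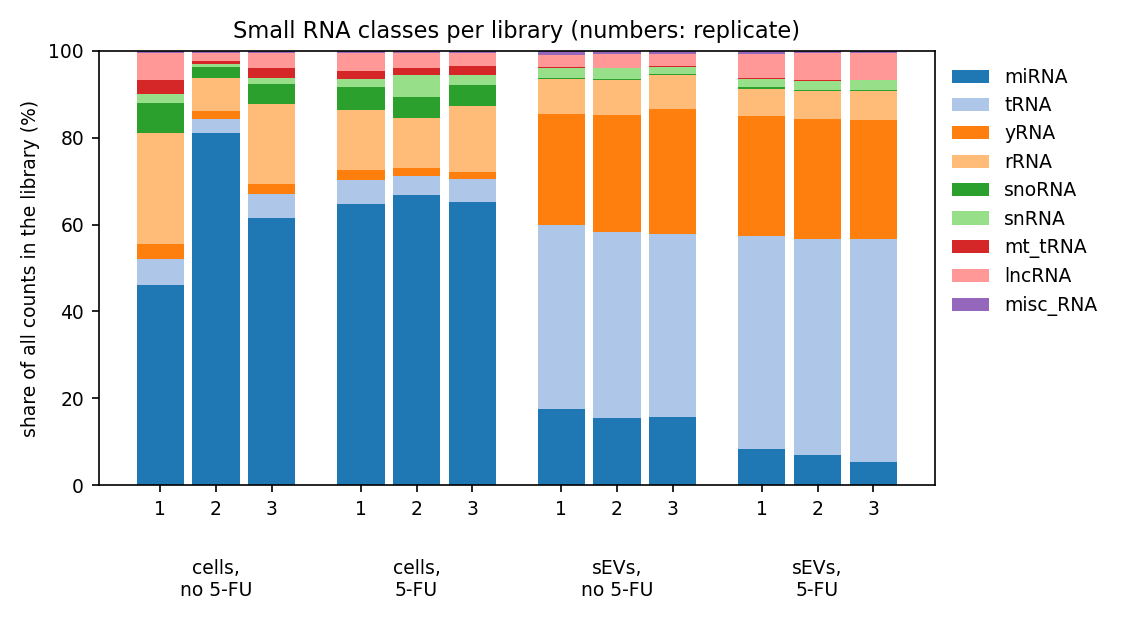
Share of all counts in each library (percent, linear axis from 0) taken by each of 9 small RNA classes, as stacked bars for the 3 replicates of each of the 4 groups. The mean miRNA share, the lowest segment, is 62.9% and 65.6% in cells without and with 5-FU and 16.3% and 6.95% in sEVs.

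Against untreated cells, sEVs of untreated cells held larger shares of Y RNAs and tRNAs and smaller shares of snoRNAs and mitochondrial tRNAs. The selenocysteine tRNA tRNA-SeC-TCA rose 289-fold, from 1.55 ± 0.266 to 448 ± 86.6 normalised CPM, counts scaled to the effective library size (SD, n = 3), with adjusted p = 1.88e-05. RNY1, the most abundant Y RNA in sEVs and chosen after its values were seen, rose 43.5-fold (log2 5.44, SE 0.35), and RNU1-132P, a copy of U1 snRNA, the splicing RNA that recognises 5′ splice sites, rose 118-fold. miR-1246, at chromosome 2, 176601024 to 176601042 on the minus strand, rose 68.3-fold (log2 6.09, SE 0.35, adjusted p = 2.92e-05), and miR-193b-3p rose 17.1-fold. miR-1246 belongs to the list of miRNAs overlapping other small RNA classes, so its reads may come from another small RNA. The let-7 miRNAs, which restrain proliferation, were on the other side: let-7f-5p fell 13.2-fold (log2 −3.72, SE 0.27) and let-7a-5p 11.2-fold. miR-21-5p, often raised in tumours, fell 5.84-fold, from 51100 ± 16900 to 8760 ± 843 CPM, and the mitochondrial isoleucine tRNA mt-TI fell 149-fold. These folds are with TMM, whose factors ran from 1.599 to 1.699 in cells and from 0.567 to 0.664 in sEVs. With total counts the rises are smaller and the falls larger. Of all counts in untreated cells and their sEVs, RNY1 held 0.642% and 10.2%, and miR-1246 0.00691% and 0.172%. For let-7a-5p these shares were 5.53% and 0.181%, and for miR-21-5p 8.51% and 0.528%.

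By class, 26 of 33 Y RNAs rose and 1 fell (camera adjusted p = 1.19e-08; adjusted p = 0.0585 with an estimated correlation). Of 53 tRNAs 32 rose and 1 fell, and of 171 snRNAs 108 rose and 28 fell, and both sets were higher by camera (adjusted p = 1.74e-05 and 3.09e-10; adjusted p = 0.54 for each with an estimated correlation). Scaled to total counts 21 tRNAs were higher and 18 lower, with a median of 0.16 against 1.57, and 77 snRNAs were higher and 41 lower, with a median of 0.79 against 2.23. Of 281 snoRNAs 228 fell and 6 rose, SNORD98 by a log2 change of −7.19, and 16 of 22 mitochondrial tRNAs fell (camera adjusted p = 4.09e-32 and 4.06e-05; adjusted p = 0.54 for each with an estimated correlation). The rRNAs rose in 10 of 18 cases and the misc_RNA class rose in 69 and fell in 25 of 131, but scaled to total counts their medians turned from 0.91 to −0.54 and from 1.24 to −0.20 (camera adjusted p = 0.00699 and 6.40e-04; adjusted p = 0.41 and 0.645 with an estimated correlation). Among lncRNA features 47 of 353 rose and 51 fell, with a median of 0.65 that turned to −0.75 with total counts (8 higher, 95 lower). miRNAs split into 158 that rose and 148 that fell of 634 (camera adjusted p = 0.559), with a median log2 difference of 0.36 that turned to −1.08 when scaled to total counts (26 higher, 289 lower). Without untreated cell replicate 3 or sEV replicate 1, 2 or 3 the miRNAs that rose numbered 82, 104, 105 and 85.

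Of the let-7 family 12 of 18 fell and 1 rose (also 12 and 1 adjusted over the list alone), and 8 of 9 members of the epithelial miR-200 family fell (8 adjusted over the list alone), miR-200c-3p 4.51-fold and miR-200a-3p 6.27-fold. Camera called both lists lower (adjusted p = 0.00422 for each; adjusted p = 0.701 and 0.54 with an estimated correlation). No other miRNA list passed camera against all features (adjusted p from 0.0613 to 0.887). Tested against other miRNAs only, let-7 and miR-200 (adjusted p = 4.09e-04 for each) and the 5-FU response (0.0019), gut epithelium (0.018) and p53-linked lists (0.0228) were lower. The adjusted p of these 5 ran from 0.118 to 0.184 with an estimated correlation. In the miR-17~92 list 4 rose and 10 fell of 19, in the gut epithelium list 1 rose and 9 fell of 22, in the p53-linked list 5 of 11 fell, and in the 5-FU response list 4 rose and 15 fell of 39. Adjusted over the list alone these counts were 4 and 10, 1 and 8, 5, and 3 and 14. Members rose in 7 of 14 cases in the list of miRNAs tied to KRAS status in vesicles, in 6 of 11 in the mirtron and Dicer-independent list and in 6 of 12 in the neural and germ cell list, where 1 fell, with the same counts adjusted over the list alone. Scaled to total counts their medians moved from 1.04 to −0.42, from 1.05 to −0.40 and from 1.45 to 0. In the list of miRNAs often reported in vesicles 6 rose and 3 fell of 13 (the same adjusted over the list alone), while with total counts 5 rose and 5 fell and the median of 1.57 was 0.11. Among them miR-320a-3p rose 4.17-fold. In the list of miRNAs overlapping other small RNAs 2 rose and 3 fell of 11 (2 and 2 adjusted over the list alone), of the blood and serum miRNAs 5 of 13 fell (3 adjusted over the list alone), and of the stromal and muscle miRNAs 1 of 4 rose, miR-1-3p, in which a log2 change of 2.09 was 0.64 with total counts. With total counts 1 rose and 33 fell in the 5-FU response list, 0 and 16 in the gut epithelium list, and 0 and 14 in the miR-17~92 list. These counts were 0 and 8 in the p53-linked list, 0 and 10 in the blood and serum list and 1 and 8 in the overlapping list. On that scale 4 rose and 6 fell in the KRAS list, 2 and 2 in the mirtron list, and 0 and 4 in the neural and germ cell list. Without untreated cell replicate 3, with TMM, 1 rose in each of the miR-17~92 and 5-FU response lists, 2 in the mirtron list and 3 in the neural and germ cell list, and without sEV replicate 3 these were 2, 2, 2 and 3.

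The edgeR quasi-likelihood test placed 954 of 1696 tested features past adjusted p 0.05, 456 higher and 498 lower in sEVs. Scaled to total counts, where the median log2 difference of all features shifted by −1.45, the calls were 198 higher and 784 lower, and 59 called features changed sign. Camera called the 5-FU response list lower without any 1 untreated cell replicate or sEV replicate 2 or 3 (adjusted p from 7.76e-04 to 0.0447), the gut epithelium and miR-17~92 lists without cell replicate 1 or 3 (0.00897 to 0.0476) and the p53-linked list without cell replicate 1 (0.0315), and it called the mirtron list higher without cell replicate 2 (0.0353). miR-10a-5p, with 7.93% of the counts in untreated cells and 3.15% in their sEVs, did not differ past the threshold with TMM (log2 0.12, SE 0.28) and was lower with total counts (−1.33). miR-92a-3p, miR-93-5p and miR-484 rose with TMM by 1.24, 0.85 and 1.28 and had log2 values of −0.21, −0.61 and −0.18 with total counts. Without untreated cell replicate 3, the calls of miR-92a-3p (0.89, adjusted p = 0.0507) and miR-484 (0.91, adjusted p = 0.0638) ended. For miR-4521, with 0 counts in the sEV libraries, the level was at least 2030-fold lower than in cells, taking a floor of 3 counts over the group.

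With 5-FU, the shares of Y RNAs and tRNAs were larger in sEVs than in cells by 3.82 and 3.31 on the log2 scale. Those of snoRNAs and mitochondrial tRNAs differed by −3.84 and −4.08 (exact permutation p = 0.1 and adjusted p = 0.113 for each of the 4). tRNA-SeC-TCA rose 170-fold in sEVs over treated cells (log2 7.41, SE 0.33, adjusted p = 1.37e-07), the Y RNA copy RNY4P20 169-fold and miR-1246 23.1-fold. let-7f-5p fell 22.3-fold (log2 −4.48, SE 0.18), let-7a-5p 14.7-fold, miR-21-5p 11.8-fold and miR-101-3p, at chromosome 1, 65058442 to 65058462 on the minus strand, 17.7-fold. The mitochondrial tRNAs mt-TI and mt-TR fell 217-fold and 142-fold. These folds are with TMM, and with total counts the rises are smaller and the falls larger. Of all counts in treated cells and their sEVs, miR-1246 held 0.0115% and 0.0688%, let-7a-5p 5.23% and 0.0911%, and miR-21-5p 8.8% and 0.191%. miR-12135, with 0 counts in sEVs, was at least 3730-fold lower, by a floor of 3 counts over the group.

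Of 36 Y RNAs 32 rose and 1 fell, of 53 tRNAs 35 rose and 8 fell, and of 151 misc_RNA features 109 rose and 5 fell, although scaled to total counts the medians of the tRNAs and the misc_RNA class turned to −0.24 and −0.30. Of 173 snRNAs 106 rose and 40 fell and of 18 rRNAs 13 rose and 1 fell, with medians of 1.41 and 1.00 that turned to −0.56 and −0.98 with total counts. On that scale 19 Y RNAs rose and 6 fell, and 16 tRNAs rose and 23 fell. The counts were 52 and 50 for the misc_RNA class, 63 and 76 for snRNAs, and 6 and 11 for rRNAs. Of 303 snoRNAs 249 fell and 14 rose, and 18 of 22 mitochondrial tRNAs fell and 3 rose. Camera called these 7 classes (adjusted p from 6.42e-21 for snoRNAs to 0.00104 for rRNAs), and the adjusted p was 0.412 for each with an estimated correlation. miRNAs were lower by camera (267 fell, 140 rose of 615; adjusted p = 0.0131; adjusted p = 0.709 with an estimated correlation), and this call ended without sEV replicate 2 (adjusted p = 0.0672). With total counts 479 miRNAs fell and 11 rose, and without treated cell replicate 1, 2 or 3, with TMM, 84, 79 and 80 rose. Of 362 lncRNA features 90 rose and 72 fell, with a median of 0.64 that turned to −1.28 with total counts (18 higher, 167 lower). Camera called them higher without any 1 treated cell replicate or sEV replicate 1 (adjusted p from 4.71e-04 to 0.0112), against 0.308 with all libraries.

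Among the miRNA lists, 15 of 18 let-7, 15 of 19 miR-17~92, 9 of 9 miR-200, 21 of 24 gut epithelium, 9 of 11 p53-linked, 28 of 38 5-FU response and 10 of 14 blood and serum members fell, while 1, 3, 0, 1, 0, 2 and 0 rose. Adjusted over the list alone these counts were the same except for 3 rises in the 5-FU response list. Camera called each of the 7 lower (adjusted p from 3.81e-04 to 0.0148; adjusted p from 0.412 to 0.59 with an estimated correlation). The KRAS list split into 5 that rose and 6 that fell of 14, the vesicle list into 6 and 5 of 13, and the overlapping list into 2 and 5 of 11. The neural and germ cell list split into 3 and 4 of 11, the stromal and muscle list into 1 and 2 of 3, and 6 of 11 mirtron and Dicer-independent miRNAs rose. None of these 6 lists passed camera against all features (adjusted p from 0.115 to 0.878; adjusted over the list alone the counts were the same but for 7 rises in the vesicle list). Tested against other miRNAs only, the mirtron list was higher (adjusted p = 0.00287; adjusted p = 0.116 with an estimated correlation). The 7 lists called above were lower in that test (adjusted p from 3.48e-04 to 0.0099; adjusted p from 0.116 to 0.214 with an estimated correlation). Without sEV replicate 2 or 3 camera called the mirtron list higher (0.0405 and 0.0403). Total-count scaling turned the medians of the KRAS, vesicle and mirtron lists from 0.12 to −1.85, from 1.57 to −0.39 and from 0.55 to −1.41. On that scale none rose in 10 of the 13 lists, 1 rose in each of the let-7, vesicle and overlapping lists, and 8 of 14 KRAS, 6 of 13 vesicle, 9 of 11 overlapping, 10 of 11 neural and germ cell and 8 of 11 mirtron members fell. Without treated cell replicate 2 or 3 or sEV replicate 1, with TMM, 1 mirtron member rose, and without treated cell replicate 1 there were 3.

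In edgeR 1203 of 1733 features passed the threshold, 542 higher and 661 lower in sEVs. Scaled to total counts (a shift of −1.96) 188 were higher and 1129 lower, and 237 called features changed sign. miR-320a-3p rose 3.71-fold with TMM (log2 1.89) and had a log2 value of −0.07 with total counts, and miR-10a-5p fell under both (−1.22 and −3.17).

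In the cells themselves, 5-FU went with fewer reads of 5.8S rRNA, a part of the large ribosomal subunit, and more reads of some H/ACA box snoRNAs, the guides of pseudouridine formation in rRNA. RNA5-8SN, a feature that joins 4 gene copies, with its position at chromosome 21, 8256781 to 8256933 on the plus strand, fell 6.32-fold (log2 −2.66, SE 0.33, adjusted p = 0.0068), from 50400 ± 20100 to 7970 ± 491 CPM (SD, n = 3). A second 5.8S entry without a position, 5.8S_rRNA, fell 5.27-fold, from 87.7 ± 19.9 to 16.6 ± 2.74 CPM. SNORA64, at chromosome 16, 1962973 to 1963106 on the minus strand within the ribosomal protein gene RPS2, rose 7.93-fold (log2 2.99, SE 0.34, adjusted p = 0.0051), from 20.7 ± 6.15 to 165 ± 26.2 CPM. SNORA3B, in an intron of the ribosomal protein gene RPL27A, rose 3.57-fold (log2 1.84, SE 0.36, adjusted p = 0.0481).

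Of 109 H/ACA box snoRNAs 5 rose and none fell (15 rose adjusted over the list alone), and 81.7% had a higher estimate with 5-FU. The other 3 were SNORA36C, SNORA47 and SNORA36A, at log2 3.76, 3.18 and 2.11, chosen after their values were seen. The number that rose was 17 without untreated replicate 1, 14 with 1 that fell without untreated replicate 2, 1 without untreated replicate 3, and 2 without any 1 of the treated replicates. Camera called the set higher (adjusted p = 2.73e-08, but 0.985 with an estimated correlation and 0.817 with fry). Of 143 C/D box snoRNAs, the guides of 2′-O-methylation, edgeR called 0 (4 at an unadjusted p under 0.05), with a median of 0.03, and camera gave adjusted p = 0.834. Camera called them higher without untreated replicate 1 (1.26e-04) and lower without untreated replicate 2 (0.00397). Camera also called all snoRNAs and the snRNAs higher (adjusted p = 1.09e-04 for each) and the rRNAs, the misc_RNA class and the mirtron list lower (0.00164, 4.96e-04 and 0.0244), with adjusted p = 0.985 for each with an estimated correlation. The call of all snoRNAs ended without untreated replicate 2 (adjusted p = 0.616), that of the rRNAs without untreated replicate 3 (0.0639), that of the misc_RNA class without untreated replicate 1 (0.186) or treated replicate 3 (0.122), and that of the mirtron list without untreated replicate 2 or 3 or treated replicate 2 or 3 (0.285, 0.0878, 0.145 and 0.122). In those sets 5 of 307 snoRNAs rose, 2 of 18 rRNAs and 2 of 123 misc_RNA features fell (24 adjusted over the list alone), and edgeR called 0 of 144 snRNAs (10 at an unadjusted p under 0.05) and 0 of 14 in the mirtron list (1 adjusted over the list alone). Without untreated replicate 2, 20 misc_RNA features fell, and without untreated replicate 3 or any 1 treated replicate edgeR called 0 of them. Of 421 lncRNA features 4 rose and 1 fell, and 0 passed without untreated replicate 3 or any 1 treated replicate; AP003778.1, which rose 5.65-fold, spans 6 tRNA genes.

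Of 685 miRNAs 5 fell and none rose, and with total counts 3 fell and 2 rose. Without untreated replicate 1, 15 fell and 3 rose, without untreated replicate 2, 11 fell and 16 rose, and without any 1 of the other 4 libraries edgeR called 0. With library sizes from miRNAs alone 54 of 662 fell and 34 rose, with a median of −0.05. miR-95-3p, in an intron of ABLIM2, fell 2.85-fold, from 71.5 ± 17.2 to 25.0 ± 0.564 CPM, and miR-328-3p fell 2.84-fold (adjusted p = 0.0481 for each, and 0.0501 and 0.0569 with total counts). miR-449c-5p, miR-3065-5p and miR-5010-3p fell by log2 2.29, 1.77 and 1.69 and were chosen after their values were seen. The abundant miRNAs did not pass: miR-10a-5p had a log2 difference of 0.49 (SE 0.28), miR-21-5p of −0.07 (SE 0.27, 0.05 with total counts) and let-7a-5p of −0.21 (SE 0.23). Apart from the mirtron list, none of the 12 other miRNA lists passed camera (adjusted p from 0.0813 to 0.997). None of their members passed the edgeR threshold with TMM or total counts, and 1 member of the 5-FU response list fell when adjusted over the list alone. With library sizes from miRNAs alone members did pass: 2 rose and 2 fell in the let-7 list, 2 and 0 in the miR-17~92 list, 3 and 2 in the gut epithelium list, 1 and 5 in the 5-FU response list, 2 and 1 in the KRAS list, and 1 and 2 in each of the vesicle and overlapping lists. On that scale 1 fell in each of the miR-200, p53-linked and mirtron lists, and tested against other miRNAs the mirtron list gave adjusted p = 0.386. Without untreated replicate 1 camera called the 5-FU response, KRAS and vesicle lists and all miRNAs lower (1.26e-04, 0.0343, 0.0085 and 6.66e-08), and without untreated replicate 2 it called the miR-17~92 list and all miRNAs higher (0.0218 and 0.0165).

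In all, 19 of 1806 features passed in edgeR, 9 higher and 10 lower with 5-FU, against 255 at an unadjusted p under 0.05, and DESeq2 gave 53. With total counts (a shift of 0.14) 28 passed, 21 higher and 7 lower. The count moved with single libraries: it was 54 without untreated replicate 1, 96 without untreated replicate 2, 1 without untreated replicate 3 (SNORA36C), 3 without treated replicate 1 (RNA5-8SN, SNORA36C and SNORA64), and 2 without treated replicate 2 or 3 (SNORA36C and SNORA64). The log2 change of RNA5-8SN stayed between −2.88 and −2.35, with adjusted p = 0.0554, 0.0839 and 0.106 without untreated replicate 3, treated replicate 2 and treated replicate 3. A simulated 2-fold change was recovered for 10.4% of features in a design of this size and spread, and a 4-fold change for 90.9%.

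**Figure D2:**
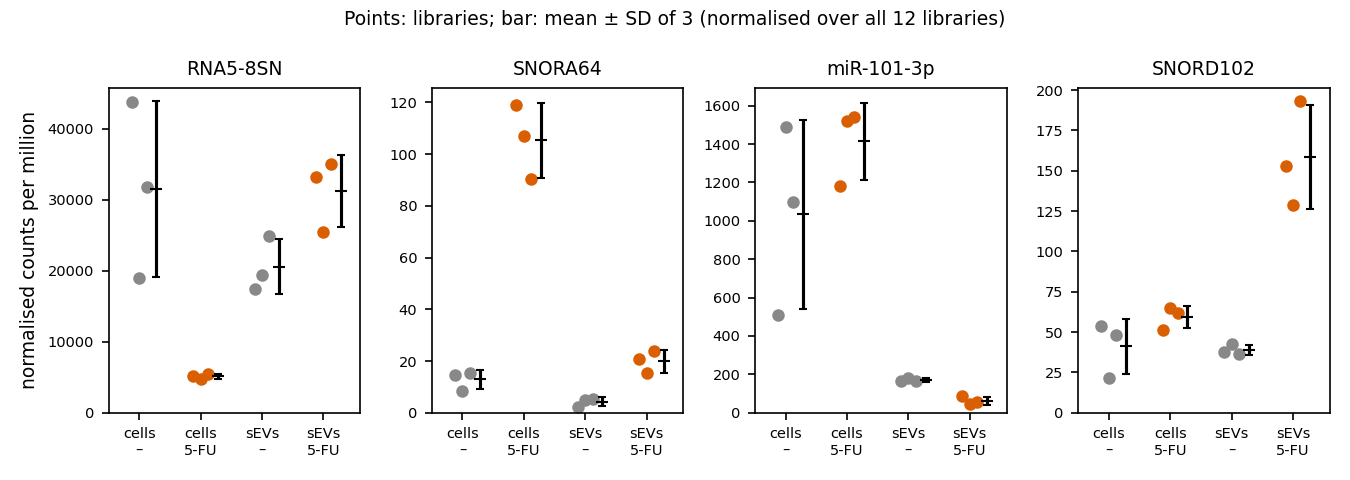
Normalised CPM (linear axes) of RNA5-8SN, SNORA64, miR-101-3p and SNORD102 in each library as points, with the mean ± SD of the 3 libraries of each group, scaled over all 12 libraries with TMM. RNA5-8SN is lower and SNORA64 higher in the treated cells, and miR-101-3p is lower and SNORD102 higher in the treated sEVs; the higher RNA5-8SN in treated sEVs shrinks to a log2 difference of 0.14 with total counts.

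In sEVs, relative to all features, 5-FU went with fewer reads of part of the miRNAs and more of part of the snoRNAs, while the Y RNA share of counts was 27.1% without and 27.6% with it (exact permutation p = 0.7). In the regrouping that counted AC073140.2 as Y RNA that share was 29.1% and 32.6% (log2 difference 0.17, exact permutation p = 0.1, adjusted p = 0.15). miR-101-3p fell 2.49-fold (log2 −1.32, SE 0.19, adjusted p = 0.00184), from 102 ± 9.61 to 41.0 ± 9.19 CPM (SD, n = 3), and miR-320d, miR-769-5p, miR-185-5p, miR-27b-3p and miR-27a-3p fell by log2 1.28, 1.24, 1.22, 1.21 and 1.15. miR-21-5p fell 1.79-fold, from 4230 ± 392 to 2360 ± 362 CPM. The C/D box snoRNA SNORD102, at chromosome 13, 27255064 to 27255135 on the plus strand in the ribosomal protein gene RPL21, rose 4.58-fold (log2 2.20, SE 0.18, adjusted p = 4.35e-04), and tRNA-Thr-TGT rose 4.92-fold. The 5.8S_rRNA entry fell 6.77-fold, whereas RNA5-8SN, chosen after its values were seen, rose 1.72-fold with TMM (log2 0.78) and had a log2 difference of 0.14 with total counts.

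Of 505 miRNAs 130 fell and 10 rose, with a median of −0.58 (camera adjusted p = 4.26e-43; adjusted p = 0.172 with an estimated correlation). Without treated replicate 3, 10 fell and 3 rose, without treated replicate 2, 66 fell and 6 rose, and without untreated replicate 2, 67 fell and 7 rose. Scaled to total counts 274 fell and 1 rose, and with library sizes taken from miRNAs alone 36 of the 505 fell and 38 rose with a median of −0.06. On that last scale the 6 miRNAs named above as falling most still fell, miR-101-3p by log2 0.82, and miR-484, at −0.15 among all features, rose (0.36). miR-186-5p, which rose 1.62-fold with TMM, had a log2 change of 0.07 with total counts.

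Of 220 snoRNAs 105 rose and none fell, with 34 of 72 H/ACA box and 67 of 129 C/D box members (38 and 74 adjusted over the list alone) and medians of 1.46 and 1.00. Camera called these 3 sets higher (adjusted p = 1.77e-18, 6.25e-11 and 3.31e-13; adjusted p = 0.189, 0.172 and 0.245 with an estimated correlation). With total counts 35 snoRNAs rose and 5 fell. With TMM, 24 rose without treated replicate 3, and 48 rose and 1 fell without untreated replicate 3. Of 34 Y RNAs 24 rose and none fell and of 136 misc_RNA features 52 rose and none fell (camera adjusted p = 2.68e-07 and 2.91e-15; adjusted p = 0.179 and 0.189 with an estimated correlation), while with total counts 6 rose and 2 fell, and 17 rose and 4 fell. Without treated replicate 3, with TMM, 7 Y RNAs and 9 misc_RNA features rose, and without treated replicate 1, 8 Y RNAs rose and 2 fell. The misc_RNA features AC016753.2, AC060812.2 and AL162390.1 are Y RNA-like, so this class and the Y RNAs may share reads and are not separate evidence. tRNAs (19 rose, 3 fell of 51), snRNAs (19 and 19 of 145), rRNAs (4 and 3 of 19), mitochondrial tRNAs (5 and 0 of 21) and lncRNA features (17 and 3 of 310) did not pass camera. They were called without single libraries, the lncRNA features without treated replicate 1 or 3 or untreated replicate 1 (5.52e-06, 0.0157 and 0.0115) and the tRNAs and mitochondrial tRNAs without treated replicate 2 (0.0171 and 0.0406) or untreated replicate 3 (0.0441 and 0.0488), all higher, and the snRNAs lower without untreated replicate 3 (0.0421). The medians of these 5 classes, 0.43, 0.35, 0.17, 0.55 and 0.55, turned to −0.20, −0.31, −0.45, −0.11 and −0.11 with total counts. On that scale 7 tRNAs rose and 15 fell, and 2 snRNAs rose and 36 fell. The counts were 0 and 9 for rRNAs, 1 and 0 for mitochondrial tRNAs, and 8 and 8 for lncRNA features.

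Among the miRNA lists, 13 of 16 miR-17~92 miRNAs fell and none rose (14 fell adjusted over the list alone), miR-93-5p by log2 0.94 and miR-106b-5p by log2 0.84. In the 5-FU response list 19 of 33 fell and 1 rose (24 and 1 adjusted over the list alone). In the gut epithelium list 10 of 19 fell, such as miR-192-5p by log2 0.96 and miR-183-5p by log2 0.99, and 11 fell adjusted over the list alone. Members fell in 5 of 16 cases in the let-7 list (10 fell and 1 rose adjusted over the list alone), 4 of 7 in the miR-200 list (6), 8 of 13 in the KRAS list (9), 3 of 10 in the neural and germ cell list (4), and 4 each of 10 p53-linked, 12 vesicle and 12 blood and serum miRNAs (4 each). Camera called these 10 lists lower (adjusted p from 1.26e-10 to 0.00226; adjusted p from 0.179 to 0.386 with an estimated correlation). Tested against other miRNAs only, the miR-17~92 list (adjusted p = 0.0355) and the 5-FU response list (0.0278) were still lower (adjusted p = 0.446 for each with an estimated correlation), and the let-7 list lay on the other side (adjusted p = 0.388). Without treated replicate 3, with TMM, none fell in the miR-17~92, 5-FU response, gut epithelium, let-7, miR-200 and p53-linked lists, and 1 fell in each of the KRAS, neural and germ cell, vesicle and blood and serum lists. Without treated replicate 2 or untreated replicate 2, 1 let-7 member fell, and in the 5-FU response list 11 and 10 fell. With total counts, 14 fell in the miR-17~92 list, 28 in the 5-FU response list, 16 in the gut epithelium list, 12 in the let-7 list, and 7 in the miR-200 list. On the same scale 11 fell in the KRAS list, 7 in the neural and germ cell list, 8 in each of the p53-linked and vesicle lists and 7 in the blood and serum list, and none rose in these 10 lists. With library sizes from miRNAs alone 3 fell and 1 rose in each of the miR-17~92 and KRAS lists, 7 and 1 in the 5-FU response list, 4 and 0 in the gut epithelium list, and 1 and 1 in the let-7 list. These counts were 2 and 0 in each of the vesicle and neural and germ cell lists, and 1 and 0 in each of the miR-200, p53-linked and blood and serum lists. On that scale the medians of the let-7, vesicle and blood and serum lists turned from −0.44, −0.44 and −0.50 to 0.09, 0.06 and 0.01. In the overlapping list 2 rose and 1 fell of 11, with miR-1291, which lies within SNORA2C, rising by log2 3.81, and 1 of 12 mirtron miRNAs fell, with the same counts adjusted over the list alone (camera adjusted p = 0.277 and 0.0556). With total counts 1 rose and 5 fell in the overlapping list, and 0 rose and 5 fell in the mirtron list. With library sizes from miRNAs alone these counts were 2 and 0, and 2 and 1. The stromal and muscle list had fewer than 3 tested members. Camera called the mirtron list lower without treated replicate 1 (0.00508) or untreated replicate 1 or 2 (0.0249 and 0.0214).

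In edgeR 413 of 1441 features passed, 255 higher and 158 lower with 5-FU. With total counts (a shift of −0.64) 430 passed, 77 higher and 353 lower, and 19 called features changed sign. The share of higher calls, 61.7% with TMM, was 46.4% with RLE factors, 42.9% in DESeq2, 49.4% with no filter and 51.5% with a minimum of 10 CPM in 3 libraries. It was 38.2% without untreated sEV replicate 3 and 39.2% without treated sEV replicate 1. Without treated sEV replicate 3, 69 of the 413 calls were left, 53 higher and 16 lower, and those of miR-21-5p (−0.93, adjusted p = 0.0743), miR-27a-3p (−1.22, 0.0554), miR-27b-3p (−1.24, 0.0615), miR-93-5p (−1.04, 0.0508), miR-106b-5p (−0.91, 0.0721), miR-183-5p (−1.08, 0.0508) and miR-192-5p (−1.03, 0.0508) ended. Without treated sEV replicate 2, 242 passed.

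**Figure D3:**
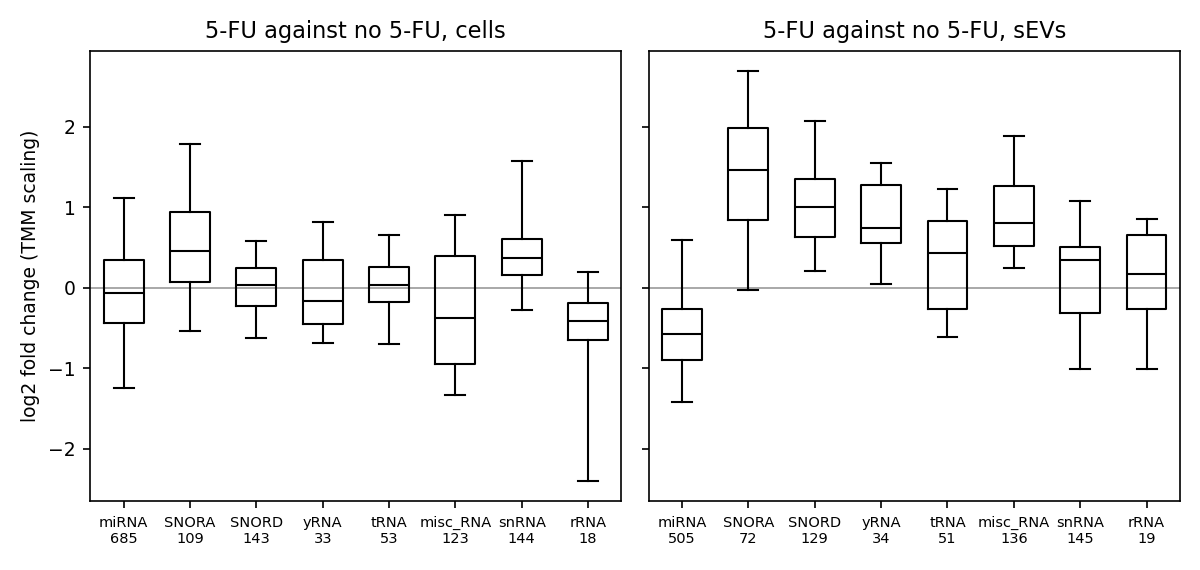
Log2 fold change with 5-FU in cells (left) and in sEVs (right) by class of small RNA, TMM-scaled, with boxes for the quartiles and median, whiskers from the 5th to the 95th percentile, and the number of tested features under each class. In sEVs the medians are −0.58 for miRNAs and 1.46 and 1.00 for H/ACA box (SNORA) and C/D box (SNORD) snoRNAs; scaled to total counts these are −1.20, 0.80 and 0.36, while the sEV medians of tRNAs, snRNAs and rRNAs turn to −0.20, −0.31 and −0.45 and the cell median of miRNAs turns from −0.07 to 0.05.

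The difference between the 5-FU effect in sEVs and that in cells compares relative read levels, so it cannot by itself show a change of export. It was past the threshold in few features. Of the features past it, RNA5-8SN had the smallest p, lower with 5-FU in cells and, with TMM, higher in sEVs (log2 difference 3.22, SE 0.39, adjusted p = 0.0021). Its share of all counts in sEVs was 1.52% ± 0.149 without and 1.67% ± 0.0337 with 5-FU, so the rise there was small on that scale. In cells the share was 4.77% ± 1.8 and 0.835% ± 0.0635. Of the miRNAs, miR-148a-3p fell in sEVs relative to cells by log2 1.74 (SE 0.42, adjusted p = 0.0477), with an effect of 0.57 in cells and −0.97 in sEVs, and miR-340-5p did so by log2 1.82, miR-7-5p by log2 1.64, miR-19b-3p by log2 1.57 and miR-148b-3p by log2 1.56. tRNA-Thr-TGT (2.29, SE 0.42) and the Y RNA-like AL162390.1 (1.92, SE 0.37) were higher in sEVs relative to cells, and the U1 copy RNU1-83P was lower (−2.40, SE 0.52). The differences of these 9 features kept their sign with total counts.

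Of 739 miRNAs 12 were lower and 1 was higher in this difference, of 169 misc_RNA features 18 were higher, and of 310 snoRNAs 9 were higher. With total counts 133 miRNAs were lower and 1 higher, 7 misc_RNA features were higher and 1 lower (a median of 0.36 against 0.92), and 4 snoRNAs were higher and 4 lower (0.08 against 0.64). Without untreated cell replicate 2, 114 miRNAs were lower and 40 snoRNAs were higher with TMM, and without any 1 of the other 11 libraries at most 3 miRNAs were lower and at most 2 misc_RNA features and 2 snoRNAs were higher. Camera called these classes (adjusted p = 5.37e-15, 2.87e-13 and 3.69e-04; adjusted p = 0.506, 0.506 and 0.575 with an estimated correlation), and the call of the snoRNAs ended without untreated cell replicate 1 (0.236) or treated sEV replicate 3 (0.142). In the miR-17~92 list 3 of 20 were lower (8 adjusted over the list alone; camera adjusted p = 2.15e-06; adjusted p = 0.506 with an estimated correlation). In the let-7 and gut epithelium lists 1 of 18 and 1 of 24 were lower (2 and 6 adjusted over the list alone; camera adjusted p = 9.39e-04 and 2.67e-06; adjusted p = 0.506 for each with an estimated correlation). Tested against other miRNAs only, the miR-17~92 (adjusted p = 0.00453) and gut epithelium lists (0.0421) were still lower (adjusted p = 0.356 for each with an estimated correlation). With total counts 11 were lower in each of these 2 lists and with library sizes from miRNAs alone 7 and 4. The let-7 list was not lower among miRNAs by camera (adjusted p = 0.77), and its median of −0.53 was −0.07 with library sizes from miRNAs alone. On that scale 1 of its members was higher and 3 were lower, while with total counts 6 were lower and 0 higher. In the 3 vesicle, mirtron and overlapping lists camera found no difference past the threshold (adjusted p = 0.143, 0.667 and 0.929), though the vesicle list was called lower without untreated cell replicate 2, treated cell replicate 2 or treated sEV replicate 1 (0.013, 0.0442 and 0.0189).

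In edgeR 52 of 2311 features passed, 37 higher and 15 lower, against 464 at an unadjusted p under 0.05, and 187 passed in DESeq2, 102 with RLE factors and 189 with total counts (a shift of −0.56), of which 22 were higher and 167 lower. With library sizes from miRNAs alone 82 of the miRNAs passed, 30 higher and 52 lower, and miR-148a-3p was among the latter (−1.33). The count was 239 without untreated cell replicate 2 and 1 without untreated cell replicate 3, any treated cell replicate, untreated sEV replicate 1 or 2, or treated sEV replicate 3. It was 10 without untreated cell replicate 1 or untreated sEV replicate 3, 15 without treated sEV replicate 1 and 8 without treated sEV replicate 2. Where 1 feature was left it was RNA5-8SN, with log2 differences from 3.18 to 3.33.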

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

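Chosen only after the result was seen were the tests of added cell RNA and of depth for the miRNA share, the tests of other rRNAs and of 5.8S copies, the count of H/ACA box snoRNAs and their difference from C/D box snoRNAs without untreated cell replicate 2, the test of length on other features, the list tests among miRNAs alone, and the counts over other splits of the libraries.

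The effect of 5-FU in sEVs differed from that in cells by the test of the difference itself in 52 features, 16 of them named in some comparison and given here. RNA5-8SN had a log2 difference of 3.22 (SE 0.39, adjusted p = 0.0021), AC016753.2 of 1.64, AC060812.2 of 1.85, AC073140.2 of 1.77, AL162390.1 of 1.92, miR-1291 of 2.80 and tRNA-Thr-TGT of 2.29. Lower in sEVs relative to cells were RNU1-83P (−2.40), miR-148a-3p (−1.74), miR-148b-3p (−1.56), miR-19b-3p (−1.57), miR-340-5p (−1.82), miR-499a-5p (−3.18), miR-7-5p (−1.64) and miR-92a-1-5p (−1.68). The fitted value of let-7g-3p was −6.41, but it has 0 counts in the sEVs of treated cells, where a floor of 3 counts over the group allows only a level at least 4.78-fold lower than in the sEVs of untreated cells. Except for RNA5-8SN each of these calls ended without untreated cell replicate 3, where 1 call was left. Of 100 drawn splits of the treatment labels 4, the real one with its 52 features included, gave as many features. The highest of the others, with 141, kept the treatment groups of cells and exchanged those of sEVs, and the next, with 102 and 68, also kept the sEV groups whole, so these counts hold the difference between the sEV groups. For the other 4 comparisons the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many features as the real 19, 413, 954 and 1203, with 0 in the highest other split.

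The same difference passed camera for 17 lists and classes. The median log2 difference was −0.53 for let-7, −1.30 for miR-17~92, −0.66 for miR-200, −0.95 for gut epithelium, −0.88 for p53-linked, −0.77 for 5-FU response, −0.62 for KRAS, −0.92 for blood and serum, and −0.82 for neural and germ cell miRNAs. It was −0.65 for all miRNAs and −0.31 for snRNAs. It was 0.80 for lncRNA features, 0.92 for the misc_RNA class, 0.64 for snoRNAs, 0.87 for Y RNAs, 0.66 for H/ACA box and 0.71 for C/D box snoRNAs, and with total counts these 6 medians were 0.29, 0.36, 0.08, 0.30, 0.08 and 0.14. The adjusted p ran from 5.37e-15 for miRNAs to 0.0255 for miR-200 and from 0.506 to 0.575 with an estimated correlation, so none held there. None passed fry either (lowest adjusted p = 0.0638). Tested against other miRNAs, 2 of the 9 miRNA lists were lower, miR-17~92 (adjusted p = 0.00453) and gut epithelium (0.0421; adjusted p = 0.356 for each with an estimated correlation), and the other 7 gave 0.259 to 0.77, so a difference of those 7 from other miRNAs was not shown. Calls ended without untreated cell replicate 1 for H/ACA box snoRNAs, all snoRNAs, KRAS and miR-200 (0.396, 0.236, 0.0611 and 0.0873), without treated sEV replicate 2 for lncRNA features and miR-200 (0.343 and 0.131), and without treated sEV replicate 3 for H/ACA box and all snoRNAs (0.235 and 0.142). The median of the stromal and muscle miRNAs was −1.86, with adjusted p = 0.0803.

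The miRNA share of sEVs was 2.37-fold lower with 5-FU. A few abundant features taking the reads would need the difference to vanish without them, but it was −1.09 on the log2 scale with the 10 most abundant features left out. The shares were then 31.6% ± 1.64 without and 15.0% ± 3.0 with 5-FU, and the SD of the log2 shares with all features was 0.23. The features left out included miR-10a-5p, miR-21-5p and let-7a-5p, so miRNA reads were removed as well. More cell RNA in the preparations of treated cells cannot by itself give a lower share, since miRNAs made up 65.6% of the counts in treated cells. The miRNAs at least 4-fold lower in sEVs than in cells had a median change of −1.09 with total counts (SD 0.83, 39 of 41 below 0). That largely restates the fall of the class, whose median was −1.20. Of other classes with larger shares in cells, snoRNAs had a median of 0.42 with total counts (35 higher, 5 lower), mitochondrial tRNAs of −0.11 and rRNAs of −0.45. Whether cell RNA was added is not decided by these. Depth hardly differed, with a ratio of 1.02. An effect of 5-FU on what is exported, and a difference between the preparations that goes with the treatment, stay open as untested.

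The 5.8S rRNA reads were lower in cells with 5-FU. The 9 other rRNA features with at least 1000 counts had a median log2 change of −0.48 (SD 0.23, lowest −0.68), which argues against less rRNA of every kind as the whole cause. Reads moving from RNA5-8SN to the second 5.8S entry would raise that entry, but it fell by 2.40 on the log2 scale (SE 0.31). That argues against a move to this entry only, and moves to other features were not tested. Both entries may share divided reads, so the second fall is not separate evidence. In sEVs their shares of counts parted with 5-FU, from 1.52% to 1.67% for RNA5-8SN and from 0.00813% to 0.000766% for the second entry. A single library is argued against by the change of RNA5-8SN nearest to 0 with each library left out, −2.35, although the call itself ended in 3 of those 6 fits. An effect of 5-FU on 5.8S rRNA or its fragments may account for it, as a hypothesis from these data, and a change in the sizes of fragments taken into the library was not tested.

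Of 109 H/ACA box snoRNAs 5 rose in cells with 5-FU, 1 without untreated replicate 3 and 2 without any 1 treated replicate, and camera called the set higher (adjusted p = 2.73e-08; adjusted p = 0.985 with an estimated correlation). Untreated cell replicate 2 is not the source of the calls, since 14 rose and 1 fell without it, nor of the difference between the medians of H/ACA and C/D box snoRNAs, which was 0.46 without it and 0.43 with it. For the median of the set itself it cannot be told apart, because the value without it, 0.27, is neither near 0 nor near the 0.46 with all libraries. Whether length plays a part was not decided. Other features of 125 to 192 nt had a median of 0.42 (SD 0.66), near the 0.46 of the H/ACA box set, as a part for length would predict. A rise of that size was thus not particular to this set. However, of these 111 features 75 were snRNAs and 29 were snoRNAs outside the SNORA names, so class and length are mixed. Within H/ACA box snoRNAs the change did not follow length (Spearman rho 0.03, and 0.16 within C/D box snoRNAs). Lengths here are those of the annotated features, not of the fragments sequenced. An effect of 5-FU, which acts on pseudouridine formation, on these guides stays open as untested.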

How the results depend on the processing

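Counting overlapping lncRNA features with other classes and testing lists among miRNAs or snoRNAs alone were the tests chosen only after the result was seen. Of 6455 values recomputed for 441 results, 5549 (86.0%) were the same by the rule of their kind. For features and lists that was the side of the threshold, and a change of sign counted only where either fit passed. Counts had to stay within 1.5 times. Part of these values could not change, so the percentage overstates how far the results withstood other processing. Shares of a pair of groups were also recomputed without libraries outside that pair. The 257 feature values for a log2 change of at least 1 came from the main fit. Among 4041 values for named features 3503 were the same, 324 were no longer past the threshold, 191 newly were, and 23 reversed; among 1464 for lists these were 1270, 123, 62 and 9. Of 710 for class shares 667 were the same, by a move smaller than the spread between replicates or, for the difference of differences, by the side of the threshold. With each library left out, the log2 difference of the miRNA share with 5-FU ranged from −1.40 to −1.09 in sEVs, and the difference of differences from −1.55 to −1.14.

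The count of features with 5-FU in cells was 29 with RLE factors, 53 with DESeq2, 55 with no filter, 34 with at least 10 CPM in 3 libraries, 6 with a replicate block and 88 among miRNA features alone, and ran from 1 to 96 with each library left out. In sEVs it was 243 with no filter, 237 with all 12 libraries in the fit, 222 with a log2 change of at least 1 and 75 among miRNAs alone (fewer features by construction in the last pair), and ran from 69 to 372. Between sEVs and cells it was 527 and 332 without 5-FU and 640 and 444 with 5-FU, for at least 10 CPM in 3 libraries and for miRNAs alone, which test fewer features. For the difference of differences it was 102 with RLE factors, 189 with total counts, 187 with DESeq2, 139 with at least 10 CPM in 3 libraries, 1 with a replicate block and 82 among miRNAs alone, and ran from 1 to 239. Where not said otherwise, the cause was not tested.

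Reversed log2 values with total counts, which by construction shift every feature, were without 5-FU miR-10a-5p −1.33, miR-92a-3p −0.21, miR-93-5p −0.61, miR-484 −0.18, miR-128-3p −1.01 and miR-372-3p −1.45. With 5-FU they were miR-92a-3p −1.29, miR-93-5p −1.95, miR-320a-3p −0.07, miR-320b −0.14, miR-484 −1.41, miR-1226-3p −1.23 and miR-1-3p −0.12. In that comparison DESeq2 reversed miR-93-5p (−0.57) and miR-484 (−0.04), no filter reversed miR-92a-3p (−0.25), miR-93-5p (−0.91), miR-484 (−0.39) and miR-1226-3p (−0.21), and at least 10 CPM in 3 libraries reversed miR-183-5p (0.06), miR-1260b (0.14) and miR-128-3p (0.50); the cause was not tested. miR-484 reversed in sEVs with 5-FU among miRNAs alone (0.36).

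Lists that reversed, by adjusted p, were C/D box snoRNAs in cells (1.83e-08 among snoRNAs alone, 0.00397 without untreated cell replicate 2, in a range of 1.26e-04 to 0.629 with each library left out) and in sEVs (0.0151 among snoRNAs alone), H/ACA box snoRNAs among snoRNAs alone in sEVs against cells (0.00142 without and 4.43e-04 with 5-FU) and in the difference of differences (0.986), let-7 in sEVs among miRNAs alone (0.388), all miRNAs in cells (0.0165 without untreated cell replicate 2, range 6.66e-08 to 0.696) and snRNAs in sEVs (0.0421 without untreated sEV replicate 3, range to 0.841). The list tests among a class alone change the features compared with; for the others the cause was not tested. Depth sets the floor of 3 counts over a group that bounds features with 0 counts, and its effect on the counts of calls was not tested.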

Other observations

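No test in this part was chosen after its result was seen. The sEVs held a few features in large amounts, all chosen after their values were seen. tRNA-Gly-GCC, which decodes glycine codons, alone made up 24.1% of the counts in sEVs without and 28.1% with 5-FU, and tRNA-Glu-CTC 6.09% and 8.68%. RNY1 and RNY4 made up 10.2% and 5.93% without, and 10.5% and 6.44% with 5-FU. In cells the largest miRNAs were miR-21-5p with 8.51% and miR-10a-5p with 7.93% of the counts without 5-FU, which held 0.528% and 3.15% in the sEVs.

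Some features were seen almost only in cells. With 5-FU miR-4521 had 6747 counts in cells and 5 in sEVs, a ratio of 1590 (95% counting interval 680 to 4890). Without 5-FU miR-12135 had a ratio of 2470 (683 to 20400), and AC051619.7, which contains a histidine tRNA gene, was at least 949-fold lower in sEVs by a floor of 3 counts over the group.

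Since 5-FU is a uracil analog, the change of a miRNA may depend on its uridine content. Across miRNAs, which are not independent replicates, Spearman's rho of the log2 change with 5-FU and the share of uridines was 0.07 in cells (n = 685, permutation p = 0.0577, adjusted p = 0.0721) and 0.04 in sEVs (n = 505, permutation p = 0.421, adjusted p = 0.421), in a family of 5 correlations. Neither is of a size that would make uridine content a main source of the change.

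GC content may separate the miRNAs of sEVs from those of cells. Across miRNAs rho of the log2 difference between sEVs and cells and GC content was 0.50 without 5-FU (n = 634) and 0.55 with it (n = 615), each with permutation p = 1e-05, the smallest that 100000 permutations can give, and adjusted p = 2.5e-05. Sorting by the cells and a bias of library preparation at low RNA input would both give this, and no test here parts them. For the change with 5-FU in sEVs rho was 0.11 (n = 505, permutation p = 0.0128, adjusted p = 0.0214), too small to decide.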
